A study of Mus musculus with 2 samples.

How the data were processed

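Total RNA longer than 200 nt from the midbrain of B6NCrl mouse embryos at 13.5 days was sequenced in 2 libraries, each made from 10 ng of RNA with added spike-in RNA, per the labels. The labels number the libraries as biological replicates 1 and 2 of 1 group and give them separate biosample entries, each of pooled male and female tissue. They list an Ambion mirVana extraction and a manual of a SMARTer ultra-low-input kit. Whether counting used strand is not given in the sources used here, so genes that overlap a partner on the other strand, such as Xist and Tsix, are uncertain.

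The authors deposited, for each library, a gene table and a transcript table on assembly mm10 with the GENCODE M4 annotation, per the text deposited with each library. The expected counts in the deposited tables are estimated reads per gene or transcript that need not be whole. The deposited TPM values are length-normalized and scaled to one common total per library with spike-ins and tRNA entries included, per the file headers and the column sums. The deposited FPKM values are scaled to length and to the number of aligned reads, per the file headers. The deposited percent values give the share of a gene's abundance assigned to each transcript, per the file headers. The lower bound of the TPM interval was also deposited by the authors, with no confidence level given. The column names are those of RSEM. The aligner, the versions and any filters are not given in the sources used here. Such tables divide reads that match several genes among them by estimation, so values of near-identical copies are uncertain.

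Each gene table held 69691 entries, of which 43346 were genes, 26248 tRNA entries and 97 spike-ins. Gene symbols, types and positions came from the GENCODE M21 annotation of GRCm38 and its name table, matched on the Ensembl identifier without its version. There were 42462 matches and 884 identifiers without one. Of the 390 list genes, 3 had no match (Ahsp, Rmst and Sox2ot) and were not analysed here. Replicate 1 held 32151659 and replicate 2 held 41915240 expected reads in all, of which 31436592 and 40215319 fell on genes. Spike-ins took 2.22% and 4.06% of the reads and were left out of scaling.

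A gene counted as detected at a TPM of at least 1 in both libraries. Differences between the libraries were taken from rounded expected counts (plus a small constant) after TMM scaling with edgeR 4.0.16 in R 4.3.3. With 1 library on each side there is no test, so genes were counted by a rule of size, at least 2-fold with a mean count of at least 50. Exact (Clopper-Pearson) 95% intervals of each ratio cover counting error only, and reads without molecular identifiers are not independent molecules. The number of list members expected past 2-fold from counting error was summed from exact binomial chances given each gene's total count. A list's median log2 ratio, over members with a mean count of at least 10, was placed among 10000 random lists of the same size matched on mean expression in 20 bins, and called outside below the 2.5th or above the 97.5th percentile. These percentiles describe the 2 libraries and are not p-values.

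Pairs of genes were compared within a library on the log2(TPM + 0.1) scale, with a two-sided limma 3.58.1 moderated test whose spread was shared with 2000 random pairs, and Benjamini-Hochberg adjustment over 36 pairs at a threshold of 0.05. A fold on this scale understates differences of low genes. The p-values cover only the spread between these 2 libraries, as do the SDs. Contrasts of lists are differences of median log2(TPM + 0.1), and the leading transcript of a gene with at least 2 transcripts and a TPM of at least 5 in both libraries is the one with the highest percent.

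The 32 lists, the 36 pairs, 25 genes for transcript use, the thresholds and most of the alternatives were fixed before the data were examined. The rule for named genes took up to 4 highest members and the lowest member of each list, members of counts of 5 or fewer, genes of the pairs, the 10 most abundant genes that were neither mitochondrial nor spike-ins, the 5 largest ratios in each direction at a mean count of at least 100, and the genes fixed for transcript use. Some of the genes this rule takes are not reported here. Alternatives were DESeq2 1.42.0 size factors, library totals, the ratio of TPM + 0.1, other count and TPM minimums, other pseudocounts, FPKM, means for medians, a 1.5-fold rule and each library alone. Removal of the trend of the ratio with GC content and length was added after seeing the data.

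The procedures were tested on simulated data. The pair test called 0% of 50 pairs with no difference, 26% at a true log2 ratio of 0.5, 88% at 1 and 86% at 2. Over 14276 simulated genes, the 2-fold rule took 0.0071% of unchanged genes, 4% at a true 1.5-fold, 56% at 2-fold and 100% at 3-fold. Of 60 simulated lists with no shift 3.33% fell outside the random range, and 100% of 20 shifted lists did. Most members of the shifted lists had a true 1.5-fold change. Simulated genes were drawn independently with a common dispersion. The rates of the 2-fold rule and of the lists therefore need not hold for genes that vary together, for genes of larger spread or for smaller shifts. Python 3.11.15 with numpy 2.4.6, pandas 2.3.3 and scipy 1.17.1 was used.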

Results

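The data describe gene and transcript levels of the mouse midbrain at embryonic day 13.5 in 2 libraries of 1 group. The series has no second tissue or age, so the questions are which genes were measured, how genes and gene groups stand to each other within the tissue, and how far the replicates differed. Values are TPM as mean ± SD with n = 2 unless stated, and positions are those of GRCm38.

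Neuronal, cytoskeletal and structural RNAs led the transcriptome. Tuba1a, an alpha-tubulin of young neurons, stood at 14096 ± 390 TPM, the nuclear RNA Malat1 at 9866 ± 165 and the imprinted gene Nnat at 7010 ± 353. Stmn1, a tubulin-binding protein, followed at 6290 ± 524, Actb at 5590 ± 808, the ferritin light chain Ftl1 at 5585 ± 37.4 and Tmsb4x at 5152 ± 457. The signal recognition particle RNAs Rn7s1 and Rn7s2 (each 15255 ± 1224) and the mitochondrial-like pseudogene Gm28437 (8583 ± 971) share reads with near copies, so their values are uncertain. Malat1 was scaled to a length of 518 nt in replicate 1, although its locus spans 5795690 to 5802672 on chromosome 19. Its level and rank depend on the annotated transcripts that its reads were assigned to, and are also uncertain. A TPM of at least 1 in both libraries was reached by 14878 of 43346 genes, 12929 of them protein-coding. A mean of at least 10 TPM was reached by 9186 genes, at least 100 by 1696 and at least 1000 by 87. The 100 most abundant genes held 27.8% of gene TPM in each library.

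Genes of midbrain identity were present at moderate levels and hindbrain Hox genes were near 0. Otx2, a transcription factor of forebrain and midbrain (chromosome 14, 48657677 to 48673819), stood at 111 ± 8.97 TPM, Meis2 at 59.4 ± 3.46, Pax3 at 26.4 ± 2.05 and Tal2 at 26.3 ± 2.32. Of 15 members of the midbrain identity list 14 were detected, the exception being Pax2 at 0.675 ± 0.262. None (0) of 12 Hox genes was detected, and the highest, Hoxb2, stood at 0.19 ± 0.0707. The midbrain list lay above the Hox list by 5.66 ± 0.07 on the log2 scale (n = 2), a value that rests on the pseudocount because the Hox genes were near 0.

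Markers of neighbouring regions were also measured. Tcf7l2, a transcription factor of thalamus and pretectum, reached 551 ± 137 TPM, Lhx9 108 ± 9.73, Lef1 68.5 ± 2.72 and Dbx1 65.3 ± 5.59, and 10 of 10 diencephalon and pretectum genes were detected. This list had a mean of medians of 38.6 TPM, above the 7.54 TPM of the midbrain identity list. Such medians depend on the make-up of each list and do not rank the regions. Lhx9, for example, is also a member of the glutamatergic list. Among forebrain genes 12 of 16 were detected, with Lhx2 at 74.9 ± 1.69, Dlx1 at 43.9 ± 0.156, Dlx5 at 18.0 ± 0.87 and Six3 at 14.9 ± 3.08. Gsx2 was lowest at 0.515 ± 0.375. The midbrain list exceeded the forebrain list by 1.05 ± 0.56 on the log2 scale, with 1.44 in replicate 1 and 0.65 in replicate 2. Of the isthmic organizer list 11 of 12 were detected, led by Cnpy1 (70.2 ± 4.93) and Spry2 (26.4 ± 7.44), and of other hindbrain markers 6 of 9, led by Gbx2 (43.0 ± 23.6) and Irx2 (33.3 ± 3.85). Gbx2 is also a member of the diencephalon and pretectum list, so its level does not by itself point to hindbrain RNA.

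Neurons and dividing progenitors were both strongly represented. The neuronal tubulin Tubb3 reached 1618 ± 85.1 TPM, the growth-cone protein Gap43 748 ± 89.9, Stmn2 726 ± 42.9 and Mapt 452 ± 56.2, and 18 of 18 pan-neuronal genes were detected. The radial glial fatty-acid binding protein Fabp7 stood at 1072 ± 83.0, Vim at 631 ± 16.4, the Notch target Hes5 at 254 ± 22.8 and Id4 at 175 ± 37.8, with 20 of 20 progenitor genes detected. All 16 genes of cell division were detected, led by Rrm2 (131 ± 16.9), Cdk1 (131 ± 13.9) and Pcna (129 ± 9.48). The pan-neuronal list lay above the progenitor list by 1.37 ± 0.10 on the log2 scale, against 1.44 and 1.29 in the single libraries.

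Among the lists of neuron classes the GABAergic one had the highest level, with a mean of medians of 40.9 TPM against 9.58 for glutamatergic, 9.55 for dopaminergic, 3.14 for serotonergic and noradrenergic (1.55 in replicate 1 and 4.73 in replicate 2) and 1.07 for oculomotor and cholinergic genes. These medians depend on the make-up of each list and do not rank the neuron classes. The glutamatergic list, for example, also holds Slc17a7 at 0.71 TPM. Gata3, a member of both the GABAergic and the serotonergic and noradrenergic lists, stood at 85.4 ± 10.96 TPM. Sox14 of the GABAergic list stood at 76.7 ± 15.3 and Gad2 at 68.1 ± 1.35. Pou4f1 and Lhx9 of glutamatergic neurons reached 111 ± 14.7 and 108 ± 9.73, and the vesicular transporter Slc17a6 60.5 ± 10.3. In the dopaminergic list 12 of 15 genes were detected, with Gfra1 at 35.8 ± 1.63, the selector Nr4a2 at 35.5 ± 4.09, tyrosine hydroxylase (Th) at 32.5 ± 20.1 and Ddc at 24.2 ± 13.4. Floor plate genes were detected in 15 of 15 cases, led by Sulf1 (41.6 ± 15.8) and Spon1 (38.6 ± 15.2). Isl1 stood at 42.9 ± 2.16, while 4 of 9 oculomotor and cholinergic genes were detected. Of the serotonergic and noradrenergic list 4 of 6 were detected, and Dbh was lowest at 0.41 ± 0.368.

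Globin transcripts were abundant and the astrocyte gene Gfap was near 0. Hba-a2 reached 4867 ± 119 TPM and the embryonic globin Hbb-y 3109 ± 21.1, and globin copies share reads. Detection covered 10 of 12 erythroid, 11 of 11 endothelial, 9 of 10 pericyte, 12 of 13 meningeal and 12 of 14 microglial genes, with Slc2a1 at 82.1 ± 5.72, Vtn at 99.1 ± 13.4, Col3a1 at 133 ± 21 and Pf4 at 33.0 ± 3.14. The choroid plexus gene Ttr stood at 89.2 ± 38.7. Gja1 led the astrocyte list (64.8 ± 5.19, 6 of 10 detected), while Gfap was listed at 0 and 0.01 TPM. Cnp led the oligodendrocyte lineage at 18.1 ± 1.79, with 9 of 11 detected. Of 10 genes of muscle, cartilage and epidermis 1 was detected, Col2a1 at 38.1 ± 9.26.

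Axon guidance genes were detected in 19 of 19 cases (Efna5 68.3 ± 6.66 TPM, Robo2 62.2 ± 5.23), and postsynaptic genes in 16 of 17 (Gria2 98.99 ± 8.15, Gabra2 36.4 ± 0.255). Imprinted genes were detected in 18 of 19 cases, with Ndn at 1056 ± 123 and Meg3 at 968 ± 43.1. Chromatin and RNA regulators were detected in 11 of 12, led by Ezh2 at 111 ± 5.51, and noncoding RNAs in 8 of 9. Of hypoxia genes 11 of 12 were detected, led by Ldha at 420 ± 15.6. Among 11 immediate early and heat shock genes 7 were detected, with Btg2 at 87.5 ± 2.02.

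**Figure D1:**
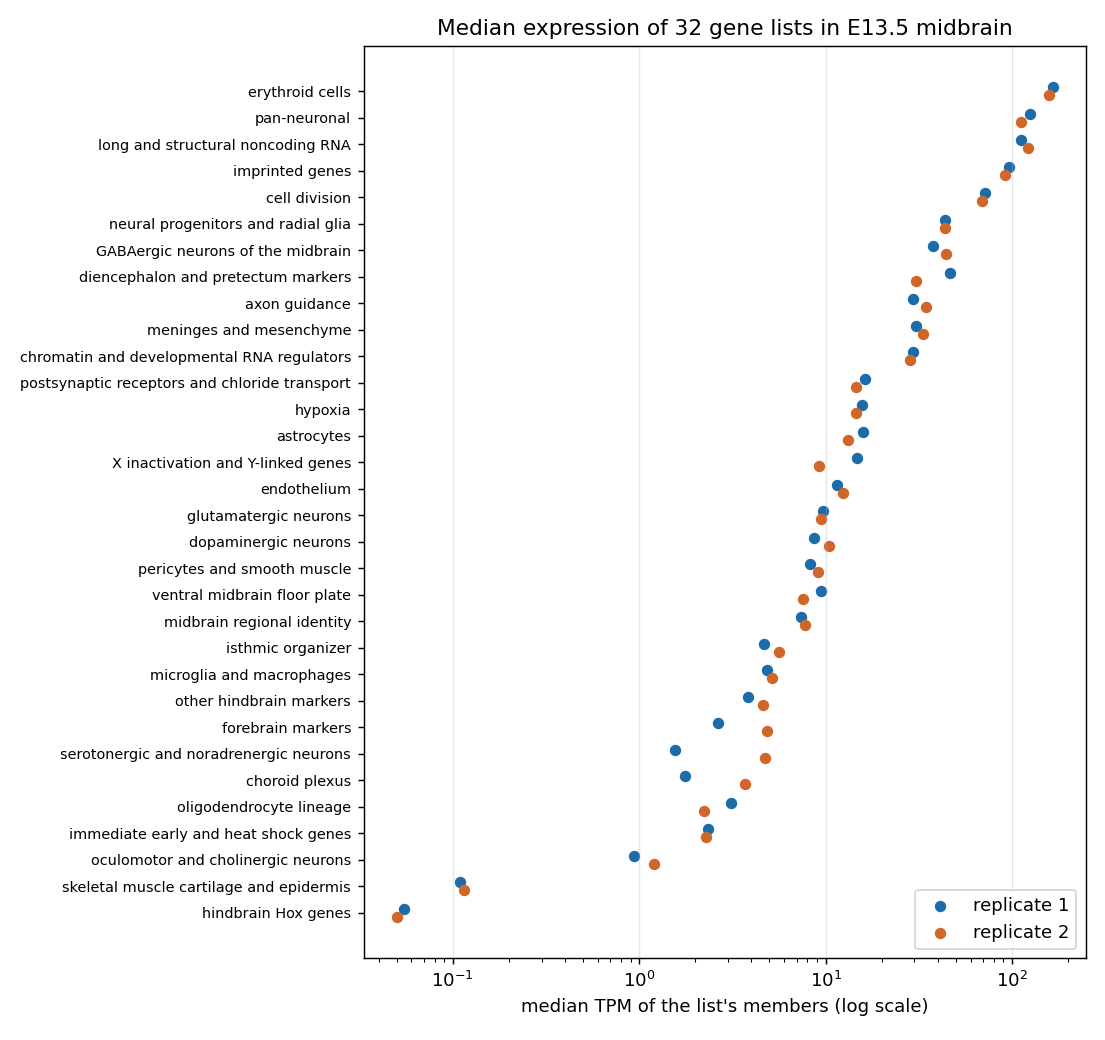
Median TPM (log axis) of the members of each of 32 fixed gene lists, with 1 point per library. Erythroid genes were highest with a mean of medians of 162 TPM, pan-neuronal genes stood at 118, and hindbrain Hox genes were lowest at 0.0525.

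Related genes were compared within each library. Forms known from immature neurons and cells exceeded those known from mature ones for sodium channels (Scn3a 7.84-fold over Scn1a, adjusted p = 0.00104), NMDA receptor subunits (Grin2b 6.44-fold over Grin2a, adjusted p = 0.00125) and polycomb enzymes (Ezh2 7.80-fold over Ezh1, adjusted p = 0.000575). The migration protein Dcx stood 8.99-fold above the maturation marker Rbfox3 (adjusted p = 0.000575). The chloride exporter Slc12a5, known from mature neurons, exceeded the importer Slc12a2 by 3.06-fold (adjusted p = 0.00245).

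Regional and transmitter pairs also stood apart. Otx2 lay 2.79-fold above Gbx2 (adjusted p = 0.0456), with log2 ratios of 0.81 and 2.15 in replicates 1 and 2. En1 exceeded En2 by 5.08-fold, Pax3 exceeded Pax7 by 5.72-fold and Lmx1a exceeded Lmx1b by 6.40-fold. Slc17a6 lay 94.5-fold above Slc17a7 (adjusted p = 0.00523), with log2 ratios of 7.77 and 5.35 in replicates 1 and 2. Slc17a7 was low (0.21 and 1.21 TPM), and the mean log2 ratio of 6.56 became 5.22 with a pseudocount of 1 and 6.86 with 0.01. Slc32a1 lay 18.6-fold above the glycine transporter Slc6a5 (adjusted p = 0.000633). Slc6a5 stood at 0.22 TPM, so the size of this ratio rests on the pseudocount. Its log2 value of 4.22 became 2.49 with a pseudocount of 1 and 4.67 with 0.01. Hes5 exceeded Hes1 by 18.9-fold, Dnmt1 exceeded Dnmt3b by 12.9-fold, Meg3 exceeded Dlk1 by 10.3-fold and Hbb-y exceeded Hbb-bs by 2.45-fold. By limma's moderated test 32 of 36 pairs passed an adjusted p of 0.05. Those that did not were Foxa2 with Foxa1 (adjusted p = 0.0612), Nr4a2 with Th (0.493), Slc17a6 with Gad2 (0.327) and Map2 with Mapt (0.0754). The calls of Otx2 over Gbx2, Pitx3 over Slc6a3 and Gad2 over Gad1 were lost when the random pairs included lower genes, and that of Otx2 over Gbx2 also with a pseudocount of 0.01.

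Most genes kept their leading transcript between the replicates. Of 7988 genes 7412 (92.8%) had the same leading transcript, with a median share of 67.0% and a median difference of 1.44 percentage points. Among 25 genes fixed for transcript use 18 kept theirs, including Ptbp2, which has 1 annotated transcript and so could not differ. The synaptic gene Snap25 gave 86.7% ± 1.64 to transcript ENSMUST00000028727 and Ncam1 gave 78.8% ± 0.233 to ENSMUST00000193547. Mapt, which encodes tau, gave 48.2% ± 0.00707 to ENSMUST00000106993 and Gnas gave 87.7% ± 1.40 to ENSMUST00000109087. Meis2 gave ENSMUST00000110908 19.3% in replicate 1 and 36.5% in replicate 2. These shares are estimates from short reads and depend on the annotated transcripts.

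The replicates were close for most genes and apart for markers of particular regions. Replicate 2 held more RNA of dopaminergic genes, with Chrna6 10.7-fold (95% interval 7.35 to 16.7), the transporter Slc6a3 5.86-fold, the selector Pitx3 5.64-fold and Th 2.63-fold (2.41 to 2.88) higher. It also held more of the cortical genes Emx1 (3.89-fold), Eomes (3.57-fold) and Tbr1 (3.14-fold). Serotonergic genes were higher in it as well, Tph2 by 3.55-fold, Slc6a4 by 3.50-fold and Fev by 2.97-fold. Replicate 1 held more Gbx2 (2.20-fold, 2.06 to 2.36; chromosome 1, 89927956 to 89931179) and more Pmch, a hypothalamic neuropeptide (3.62-fold, 3.03 to 4.36). No p-value is given because each side has 1 library.

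Of 14366 genes with a mean count of at least 50, 104 differed at least 2-fold, 73 higher in replicate 2 and 31 higher in replicate 1, and 99.3% lay within 2-fold. The median absolute log2 ratio was 0.10. Across detected genes, which are not independent replicates, log2 TPM correlated at 0.992 (Pearson). The counts differed by more than sampling noise (chi-square over degrees of freedom 11.2), so they were not taken for duplicates, and edgeR's common coefficient of variation was 0.0839. Lgi3 was 5.96-fold higher in replicate 2 (4.15 to 9.09). Among the largest differences, Gm26920, Rpl21-ps15, Gm4294 and 2 identifiers without a symbol hold fractional or 0 counts that near copies could share. D130058E05Rik, 3.16-fold higher in replicate 1, overlaps Gbx2. These are uncertain.

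Of 31 lists with enough reads 16 had a median ratio outside the range of matched random lists, 14 higher in replicate 2 and 2 higher in replicate 1. Serotonergic and noradrenergic genes had a median log2 ratio of 0.95 although 2 of 6 members, Dbh and Slc6a2, were over 2-fold higher in replicate 1, choroid plexus genes 0.60 (7 of 7 positive), floor plate genes 0.50 (12 of 15) and forebrain genes 0.36 (13 of 16). The median floor plate level was nonetheless lower in replicate 2 (7.61 against 9.48 TPM), since the middle member, Rspo2, went the other way. The dopaminergic median was 0.20 (13 of 15 positive, 6 at 2-fold or more). Median shifts toward replicate 2 were also seen for glutamatergic (0.33), GABAergic (0.32), axon guidance (0.24), meningeal (0.23), progenitor (0.19), endothelial (0.16), midbrain identity (0.15) and erythroid genes (0.12). The median TPM of the glutamatergic list (9.485 against 9.675) and of the erythroid list (158 against 165) was slightly lower in replicate 2. TPM totals include spike-ins, which took 5.36% of TPM in replicate 1 and 9.39% in replicate 2. This scaling lowers gene TPM in replicate 2, so differences this small do not show a reversal. The muscle, cartilage and epidermis list (0.59) rests on 3 members. Postsynaptic genes were higher in replicate 1 (-0.11), as was the X and Y list (-0.85). Over the lists inside the range, pan-neuronal genes stood at -0.04, cell division at -0.03 and the diencephalon and pretectum list at 0.06. Bootstrap intervals of the median over members, computed after the data were seen, spanned 0 for 6 of the 16 lists: the glutamatergic, serotonergic, axon guidance, postsynaptic, X and Y, and muscle, cartilage and epidermis lists. With the trend of the ratio with GC content and length removed they spanned 0 for 10 of the 16, adding the floor plate, forebrain, midbrain identity and endothelial lists. With means in place of medians the serotonergic, endothelial and muscle, cartilage and epidermis lists fell inside the range.

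Sex-linked genes differed in opposite directions. The Y-linked genes Eif2s3y, Ddx3y, Kdm5d and Uty stood at 57.0, 19.1, 14.3 and 11.8 TPM in replicate 1 and at 30.0, 9.40, 7.74 and 6.97 in replicate 2. Xist, the RNA of the inactive X (chromosome X, 103460366 to 103483254), stood at 15.1 and 28.4 TPM. Both libraries came from pooled male and female tissue.

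**Figure D2:**
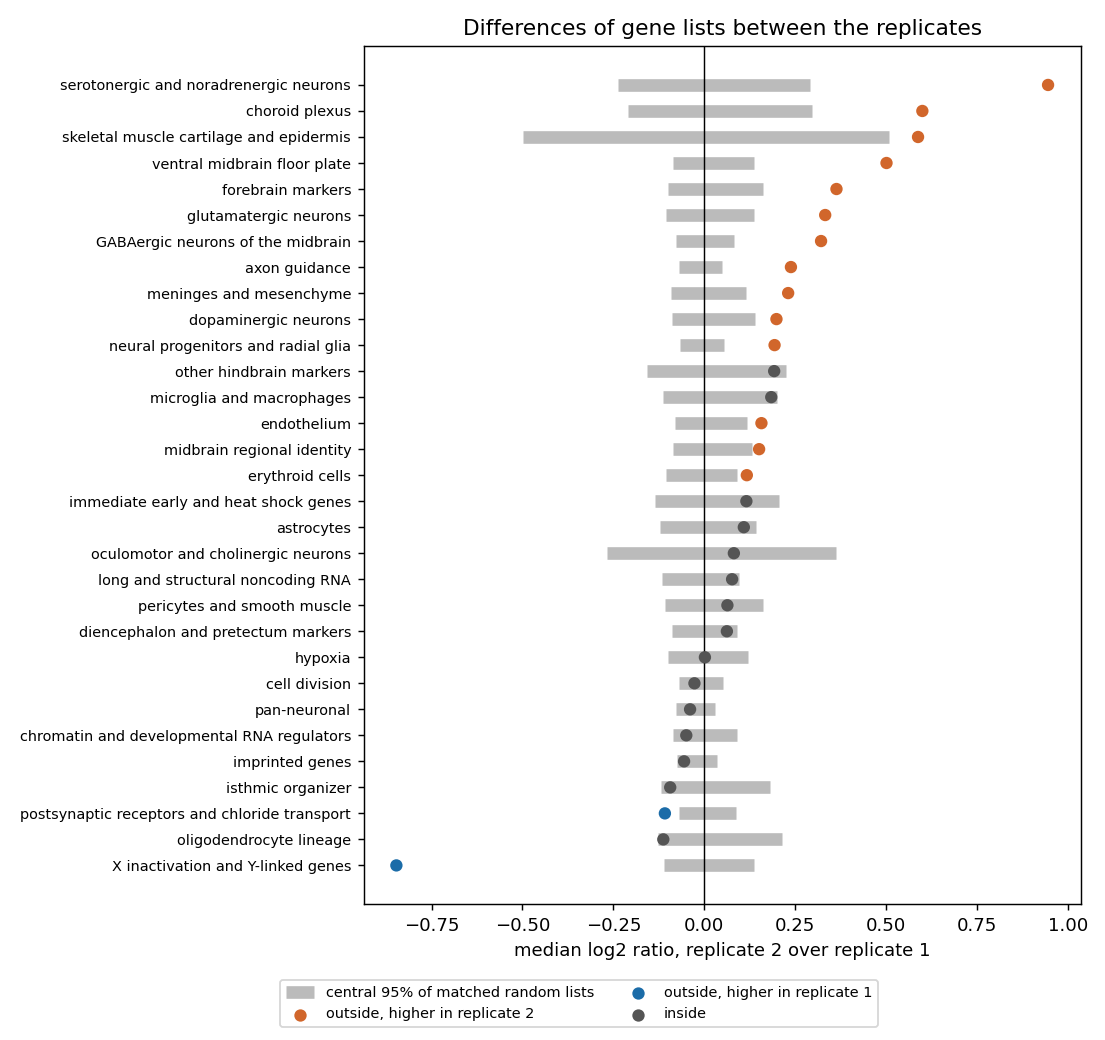
Median log2 ratio of replicate 2 over replicate 1 for 31 gene lists (points), with the central 95% of 10000 matched random lists (grey bars). Points outside the bars number 16, from -0.85 for the X and Y list to 0.95 for the serotonergic and noradrenergic list.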

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

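The tests with further marker genes were chosen after the difference between the libraries was seen, with their bounds written before those genes were examined. The bootstrap intervals, the number of genes expected from counting error, the solved share of males and the test with X-linked escape genes were chosen after the result was seen.

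Spike-in RNA, which was added on purpose, gave 715022 reads in replicate 1 and 1699859 in replicate 2. Spike-in entries were not compared above and were left out of the scaling of counts. They are part of the TPM totals, at 5.36% of TPM in replicate 1 and 9.39% in replicate 2, so TPM values above depend on them. tRNA entries, also not compared above, gave 23.54 and 22 reads.

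In 5 regional lists 17 genes differed at least 2-fold, 15 dopaminergic, floor plate, serotonergic and forebrain genes higher in replicate 2 and 2 (Gbx2 and the noradrenergic Slc6a2) higher in replicate 1, with the diencephalon and pretectum list as a whole inside the random range (5 of 10 positive), and different tissue boundaries at dissection are a candidate explanation. Further cortex genes had a median at the 99.97th percentile of matched random lists (9 of 9 positive, bootstrap interval 0.07 to 0.46 on the log2 scale), and further thalamus genes at percentile 0 (7 of 8 negative, -0.56 to -0.01). Further hypothalamus genes lay at percentile 2.21, barely past the bound of 2.5, with members in both directions and an interval that spans 0. The prediction for ventral midbrain genes was not met (percentile 93.46, inside the random range); its interval of -0.10 to 0.67 reaches past the random range, so by that criterion, added after the value was seen, this part remains open. The median absolute log2 ratio of the 17 genes was 1.59 after the GC and length trend was removed (1.65 before). The fitted trend had an SD of 0.065 on the log2 scale, so its removal could hardly undo differences chosen at 2-fold or more. This comparison shows only that the trend as fitted is too small to be the whole cause. Counting error of independent reads alone would put 0.00102 of the 56 members with a mean count of at least 50 past 2-fold, against 17 seen. Uneven amplification of the RNA and a biological difference between the pools were not tested.

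Y-linked genes and Xist differed in opposite directions, and different shares of male and female embryos may account for it. The ratios can be solved for a share of males of 67.7% in replicate 1 and 36.8% in replicate 2, a calculation that assumes equal expression per embryo. Ratios in opposite directions always have such a solution, so the calculation restates the pattern and does not test the explanation. Genes that escape X inactivation had a median at percentile 78.1, inside the random range, which leaves that test open. After the GC and length trend was removed the median absolute log2 ratio was 0.77 (0.90 before). The fitted trend had an SD of 0.065 on the log2 scale, so its removal could hardly have undone the pattern. This shows only that the trend as fitted is too small to be the whole cause. For 5 of 5 genes the counting interval, which covers counting error only, excluded 1.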

How the results depend on the processing

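Removal of the trend with GC content and length was chosen after seeing the data; the other settings were planned. The midbrain over Hox contrast was 3.02 with a pseudocount of 1, 5.83 with means and 5.20 with FPKM, and no value could be had at a mean TPM of at least 1, since no Hox gene was left. The pan-neuronal over progenitor contrast was 1.61 with means. The count of genes at 2-fold was 538 at a mean count of at least 10, 26 at 200 and 4947 with no filter, and 475 genes passed at 1.5-fold. These follow from how many genes each rule admits. With the ratio of TPM + 0.1 the split of genes at 2-fold was 64 higher in replicate 2 and 39 higher in replicate 1 (73 and 31 in the report). The leading transcript was shared by 4644 genes at a TPM of at least 20, where fewer genes were tested. The cause of the other changes was not tested.

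The 16 lists outside the random range were the same 16 with DESeq2 size factors and library totals. At a mean count of at least 50, 17 lists lay outside, 15 of them among the 16, with 14 higher in replicate 2 and 3 higher in replicate 1. That setting gained the other hindbrain markers (higher in replicate 2) and the oligodendrocyte lineage (higher in replicate 1). The muscle, cartilage and epidermis list was not tested there. With the GC and length trend removed 19 lists lay outside, 15 of them among the 16, and the split moved from 14 higher in replicate 2 and 2 higher in replicate 1 to 13 and 6. The 4 lists gained (isthmic organizer, oligodendrocyte lineage, imprinted, and chromatin and RNA regulators) were higher in replicate 1. The ratio correlated with GC content at 0.33 (Spearman, across genes), so small list shifts may carry that trend. With the trend removed 93 genes differed at least 2-fold, against 101 before, among the 14271 genes with a GC value. Foxa2 over Foxa1 and Mapt over Map2 passed the threshold with a pseudocount of 1. Pairs past the threshold numbered 29 to 34 over the settings that tested all 36, and 28 of 32 where both genes had a mean TPM of at least 1. Each library alone gave the direction of the mean for 35 of 36 pairs. The exceptions were Slc17a6 over Gad2 in replicate 1 and Nr4a2 over Th in replicate 2, neither past the threshold. Leaving out 1 library ends any comparison between the libraries.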

Other observations

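The raphe and spike-in values below were chosen after the replicate differences were seen. Further raphe genes had a median log2 ratio of 0.42 at percentile 96.4 of matched random lists, inside the random range, with Gchfr 3.48-fold higher in replicate 2. Of 7 choroid plexus genes 4 had a counting interval of the ratio above 1, Clic6 (2.54-fold higher in replicate 2), Kcne2 (2.46), Ttr (1.95) and Sostdc1 (1.52). The intervals of the other 3, Folr1, Kl and Aqp1, included 1. Spike-in TPM was 1.82-fold higher in replicate 2 over 45 spike-ins with at least 50 reads, and levels reported here are relative to all RNA in a library, not absolute amounts.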
